A study of Mus musculus with 12 samples.

How the data were processed

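Total RNA from 12 samples of primary mouse embryonic fibroblasts was labelled with biotin and hybridised to Illumina mouse BeadChips, 1 array per sample, per the labels. The labels give 3 groups of 4 samples, numbered 1 to 4 in each group: cells that carry GFP, EWS/WT1+KTS or EWS/WT1-KTS from a lentiviral vector that tetracycline switches off, grown without tetracycline. Per the series' design text the fibroblasts came from 4 pools made separately.

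The deposited table of unnormalised values gives an intensity for each of 45281 probes on each array, on a linear scale and not scaled between arrays. Beside each intensity the authors deposited a detection score from 0 to 1. Its header calls it a p-value, but the brightest probes carry 1, so 1 minus the score was taken as the detection p. The scanner software and any background step before export are not given in the sources used here. A second table holds the authors' log2 intensities. limma is named in the submitters' processing notes without a version or settings. The values of that table lay within 0.0194 log2 units of the neqc values computed here at every probe, so scale, centring and direction could be read from the comparison. Its column medians all lie between 4.54 and 4.55.

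Intensities were processed with limma 3.58.1 in R 4.3.3. Its function neqc corrected the background by normexp with negative-control statistics inferred from the detection p, added an offset of 16, normalised between arrays by quantiles and took log2. Probes with a detection p under 0.05 on at least 4 arrays were kept, which left 18061. Gene names came from GEO's platform annotation: 34885 probes had 1 symbol, 18 had several and 10378 had none here. Through Entrez IDs 34807 probes matched the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. Each symbol was represented by its kept probe with the highest mean over all arrays, and a probe without a single symbol stood for itself. This gave 12533 features, 10120 of them named. A probe is a short stretch of a transcript, so other probes of the same gene can read other transcript forms.

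Each of the 3 comparisons was taken from a limma fit (lmFit and eBayes, two-sided) of all 12 arrays with group means only, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05 on the adjusted p. Where a gene was undetected on all arrays of a group, its fold is given as at least N-fold. This sets the mean of the brighter group against the mean, per array of the dimmer group, of the higher of the gene's own value and the lowest value among detected probes. Because the arrays number 4 per group, their number limits the precision of every value.

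The replicate numbers pair the samples across groups. The labels do not state that the number marks the pool, so pool stands below for the arrays of 1 number. Deviations from the group means correlated at r = 0.43 to 0.75 in all 12 pairs of arrays with the same number and at r = -0.61 to 0.15 in pairs of other numbers from different groups, and 12 of 12 arrays matched best an array of their own number. These are correlations across genes, which are not independent replicates. The fit with the replicate number as a block is therefore printed beside the counts over all genes that it moved by over 1.5 times and beside the calls it changed among the lists and genes reported. The median standard error of a log2 fold change was 0.24 without the block and 0.16 with it.

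Named genes followed a rule fixed, like the design, the gene lists and most of the other settings tried, before the data were examined. For each comparison it takes the 12 largest rises and the 12 largest falls among genes past the threshold whose groups do not overlap, leaving out clone and model names. From each gene list with a set-test call or at least 3 called members it takes up to 3 called members per direction. It always takes a set of 13 genes of the fusion, the Wnt pathway, the p53 pathway and reported targets where measured. Named genes outside this rule were chosen after their values were seen. The 30 gene lists were tested with camera at a preset correlation of 0.01, over the 27 lists with at least 5 measured members. Each call is printed with its adjusted p under an estimated correlation.

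The steps were tested on simulated data made from the real means, pool effects and residual spread. For EWS/WT1+KTS against GFP over 12533 features, with 200 of them changed, the fit without the block recovered 24.0% of genes changed by 1 log2 unit, 91.0% changed by 2 and 99.0% changed by 3. Of genes changed by 0.5 log2 units it recovered 0%, and the fit with the block 17.8%, so a gene that did not pass can have changed by that much. With the block 91.2% of genes changed by 1 log2 unit were recovered, but 7.5 of 162 calls per simulation were false on average, against 0 of 107 without it. Lists were tested on separate data simulated in the same way, with no gene changed outside a planted list of 20 genes shifted by 1 log2 unit. The planted list was found in 10 of 10 simulations, and 0 of 260 unchanged lists were called. These lists were random genes with independent residual noise. The simulation therefore cannot show how often camera calls unchanged lists whose genes vary together.

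Alternatives covered the background correction and scaling, the authors' log2 table, the detection filter, the choice of probe, the variance model, array weights, the arrays in the fit, the replicate block, each array left out in turn and a threshold on the fold. Chips are not named in the files used here, so no chip could be tested as a batch. No column of sample values was left unused.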

Results

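Expression was measured on 12 arrays from primary mouse embryonic fibroblasts of C57BL6 background. EWS/WT1 is the fusion protein of desmoplastic small round cell tumour, in which the transcription-activating part of EWS is joined to the zinc fingers of the transcription factor WT1. Alternative splicing inserts the amino acids lysine, threonine and serine (KTS) between zinc fingers or leaves them out, and the isoforms are known to bind DNA differently. Fibroblasts carried EWS/WT1+KTS, EWS/WT1-KTS or, as the control, GFP, with 4 samples in each group. Between 34.3% and 39.4% of probes were detected per array, and the 75th percentile of raw intensity ran from 108 to 199. The series title names loss of p53 and canonical Wnt signalling as the study's subjects.

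No probe could be taken as a reading of the fusion transcript itself. Ewsr1 had 2 named probes, detected on at most 1 array, and Wt1 and Trp53 had 0 named probes in the annotation used. Whether a probe without a gene name reads the fusion was not tested, so the transgene gave no check of the labels.

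The comparison of EWS/WT1+KTS with GFP asks which transcripts the isoform with the insertion changes. Genes silent in the control cells appeared with EWS/WT1+KTS. Calb2, which encodes the calcium-binding protein calretinin, rose at least 72.4-fold, from a log2 intensity of 4.41 ± 0.22 (SD, n = 4) to 11.10 ± 1.19 (SD, n = 4). Crym, a thyroid hormone binding protein, rose at least 48.4-fold and C2cd4a at least 42.4-fold. The serotonin transporter Slc6a4 rose at least 18.9-fold and the dopamine transporter Slc6a3 at least 13.6-fold.

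The collagen gene Col23a1 rose at least 18.1-fold, the secreted airway protein gene Bpifb1 at least 17.2-fold and the epidermal gene Dmkn (dermokine) at least 12.5-fold. Cpne6, a copine, rose at least 12.7-fold. The other 3 of the 12 largest rises were detected in GFP cells too. Ccdc114, a ciliary dynein docking protein, rose 28.4-fold (log2 fold change 4.83 ± 0.34, SE) and Gldn (gliomedin) 26.5-fold, each detected on 3 of the 4 GFP arrays. Serping1, the inhibitor of complement C1, rose 18.6-fold (4.22 ± 0.58, SE). limma's adjusted p for these 12 genes lay between 5.18e-07 and 0.00186. All 8 of the 12 genes with another kept probe (Calb2, C2cd4a, Ccdc114, Slc6a4, Bpifb1, Col23a1, Serping1 and Dmkn) differed less by that probe than by the brighter probe used; in log2 units C2cd4a differed by 2.78, Col23a1 by 2.81, Ccdc114 by 1.91, Slc6a4 by 1.62 and 1 further probe of Dmkn by 0.03.

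Over 12533 features, 81 were higher and 1 was lower with EWS/WT1+KTS by limma. With the replicate block 245 were higher and 35 lower, and all 82 calls were among them. The groups of all 82 did not overlap, and each moved the same way in all 4 numbered pools. For features not selected, chance parts the groups in 2.86%. The calls were selected by their difference on these same arrays, which largely ensures both traits, so neither is further evidence. Of the 81 that rose, 35 were undetected on every GFP array. The single lower feature was the probe ILMN_2476405, unnamed here and chosen after its values were seen. It was detected on all 4 GFP arrays, at 10.60, 9.44, 5.56 and 8.65 in replicates 1 to 4, and on 0 arrays of either isoform. It was at least 12.9-fold lower with EWS/WT1+KTS (limma's adjusted p = 0.0175) and also with EWS/WT1-KTS (adjusted p = 0.0431). The call with EWS/WT1-KTS ended when any 1 array other than GFP replicate 3 was left out. That with EWS/WT1+KTS ended without its replicate 1 or its replicate 4. Both ended without background correction, with a normexp offset of 50 and with median scaling. The files used here give neither its gene nor its sequence, so whether it reads the GFP vector and not a mouse gene was not tested.

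**Figure D1:**
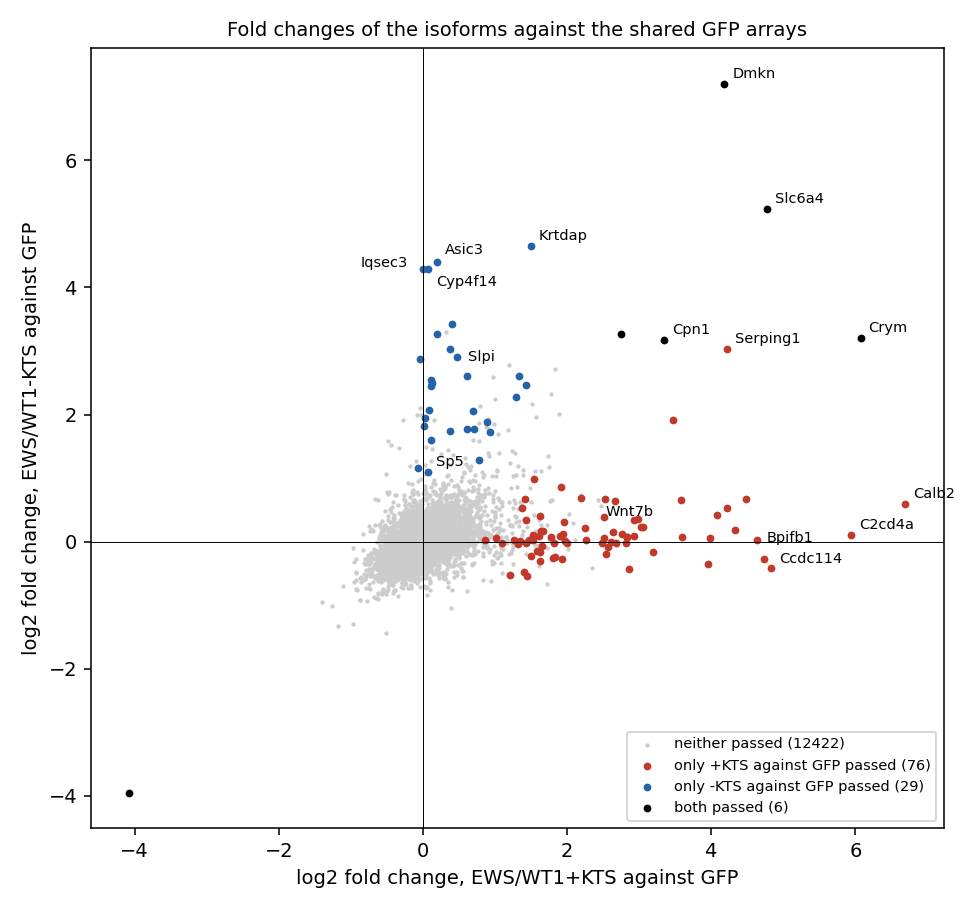
Each point is 1 of 12533 features, with its log2 fold change for EWS/WT1+KTS against GFP on the horizontal axis and for EWS/WT1-KTS against GFP on the vertical axis, coloured by which comparison passed an adjusted p of 0.05. Most features that rose lie along 1 axis, 6 features passed in both comparisons, and the only point far below 0 on both axes is the unnamed probe.

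Wnt genes were tested as lists fixed in advance. Of 20 measured Wnt ligands, receptors and co-receptors, 1 rose with EWS/WT1+KTS and 19 did not pass, and 1 also passed adjusted over the list alone. The gene was Wnt7b, a secreted Wnt ligand, which rose by 2.63 ± 0.34 (SE) on the log2 scale (adjusted p = 0.00107) and was detected on 1 of 4 GFP arrays. The list was higher by camera (adjusted p = 7.82e-05), with 15 of 20 fold changes above 0, and the adjusted p was 0.0509 with an estimated correlation. The blocked fit called 2, Wnt7b and Wnt10b. Of 20 measured Wnt/beta-catenin target genes 0 passed over all genes and 2 adjusted over the list alone. The target list was higher by camera (adjusted p = 0.00465, and adjusted p = 0.208 with an estimated correlation). With the replicate block 2 targets rose, the Wnt inhibitor Wif1 (log2 fold change 1.93, adjusted p = 0.0380) and Sox9 (1.09, adjusted p = 0.00278), both named after their values were seen. Axin2, a standard readout of beta-catenin signalling, stood at 0.39 ± 0.37 (SE) and did not pass.

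Other lists were higher by camera without single genes past the threshold. Of 29 matrix genes 0 passed over all genes or adjusted over the list alone, 24 lay above 0, and the adjusted p was 0.00465, or 0.614 with an estimated correlation. The blocked fit called 4 matrix genes higher, namely Col1a2, Col6a2, Mfap5 and Eln, the elastin gene (log2 fold change 2.69, adjusted p = 3.08e-06). Of 18 senescence-associated genes 0 passed over all genes and 2 adjusted over the list alone, with an adjusted p of 0.000145 for the list and adjusted p = 0.0884 with an estimated correlation. The blocked fit called 3 of them, Ccl7, Cxcl1 and Igfbp3. Of 18 genes of the TGF-beta response 0 passed over all genes and 2, Tgfbi and Il11, adjusted over the list alone. That list had an adjusted p of 0.0226, and adjusted p = 0.208 with an estimated correlation, and the blocked fit called 4 of its genes higher, Tgfbi, Il11, Tgfb1 and Tgfb2. Its median of 0.11 turned to -0.04 with median scaling, which moved the median of all features to -0.17. The single genes of these lists were named after their values were seen.

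Of 10 macrophage markers 0 passed over all genes or adjusted over the list alone, 8 lay above 0, and camera called the list higher (adjusted p = 0.00465, and adjusted p = 0.492 with an estimated correlation). In the fit with the replicate block Laptm5, a lysosomal protein of blood cells, rose by 2.42 on the log2 scale (adjusted p = 0.000175; named after its value was seen). Kit, the stem cell factor receptor and the 1 called gene of 5 haematopoietic markers, rose at least 4.32-fold (adjusted p = 0.0198) and was named after its value was seen; that list did not pass (adjusted p = 0.131). The chondrocyte and osteoblast list (adjusted p = 0.0133), hedgehog targets (0.0175), Notch targets (0.0421) and interferon response genes (0.0482) were higher and muscle genes lower (0.0421), with adjusted p = 0.208, 0.208, 0.323, 0.714 and 0.369 with an estimated correlation. Of their 10, 7, 7, 27 and 10 measured genes 0 passed over all genes, and adjusted over the list alone 2 passed in the chondrocyte list and 0 in the others. The blocked fit called 3 of the chondrocyte list, Acan, Sox9 and Sp7, also named after their values were seen. The chondrocyte list's median of 0.07 turned to -0.01 with median scaling. The interferon and Notch calls ended under 2 of 3 other scalings and the muscle call under all 3. The authors' log2 table, nearly the same values as those used here, could not test them. With the block camera also called Wnt antagonists (adjusted p = 0.0342) and p53 target genes (0.0199) higher, with adjusted p = 0.297 and 0.141 with an estimated correlation. In each 1 gene passed in the blocked fit, Wif1 and Sesn1, named after their values were seen.

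The calls of EWS/WT1+KTS fell to 51 without its replicate 1 and to 54 without its replicate 4. Differences from the GFP signal at background shrank without background correction, for Calb2 from 6.69 to 4.56 log2 units. The count was then 51, and it was 30 with median scaling and 14 among features detected on all 12 arrays.

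The comparison of EWS/WT1-KTS with GFP asks the same of the isoform without the insertion. Dmkn rose most, at least 102-fold, from 4.38 ± 0.05 (SD, n = 4) to 11.59 ± 0.54 (SD, n = 4). Krtdap, a keratinocyte differentiation gene beside it on chromosome 7, rose at least 17.1-fold. Slc6a4 rose at least 26.1-fold, and another transporter of the same family, Slc6a12, for betaine and GABA, rose 9.58-fold. The acid-sensing ion channel gene Asic3 rose 21.1-fold (log2 fold change 4.40 ± 0.31, SE), the synaptic gene Iqsec3 at least 13.5-fold and Cbln1 (cerebellin) 10.8-fold (3.43 ± 0.53, SE).

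Cyp4f14, a cytochrome P450, rose at least 13.7-fold, Crym at least 6.60-fold and Pramel17 at least 6.13-fold. Cpn1, a subunit of the plasma enzyme carboxypeptidase N, rose 8.99-fold and the secreted protease inhibitor Slpi 7.47-fold. The adjusted p of these 12 genes lay between 1.45e-07 and 0.0108. Asic3 and Cpn1 were detected on 2 of 4 GFP arrays, Slc6a12 on 1, and Cbln1 and Slpi on 3. All 5 genes with another kept probe (Dmkn, Slc6a4, Krtdap, Asic3 and Cpn1) differed less by it, in log2 units Slc6a4 by 1.93, Krtdap by 1.62, Cpn1 by 1.95 and Asic3 by at most 3.09; of the 2 further probes of Dmkn 1 differed by 7.16 and 1 by 0.21. Cbln1 did not pass without EWS/WT1-KTS replicate 1 (adjusted p = 0.0534), without background correction (0.122) or with a normexp offset of 50 (0.0547). Without background correction Pramel17, Crym and Cpn1 did not pass either, Crym did not with an offset of 50 (0.0610), and Slpi did not with median scaling (0.0954).

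In all, 34 features were higher and 1, the probe ILMN_2476405, was lower by limma. That lower call ended when any 1 array other than GFP replicate 3 was left out. With the replicate block 113 were higher and 17 lower, including all 35 calls. No call had overlapping groups and each kept its direction in all 4 pools, which the selection by that difference largely ensures. Of the 34, 15 were undetected on every GFP array.

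**Figure D2:**
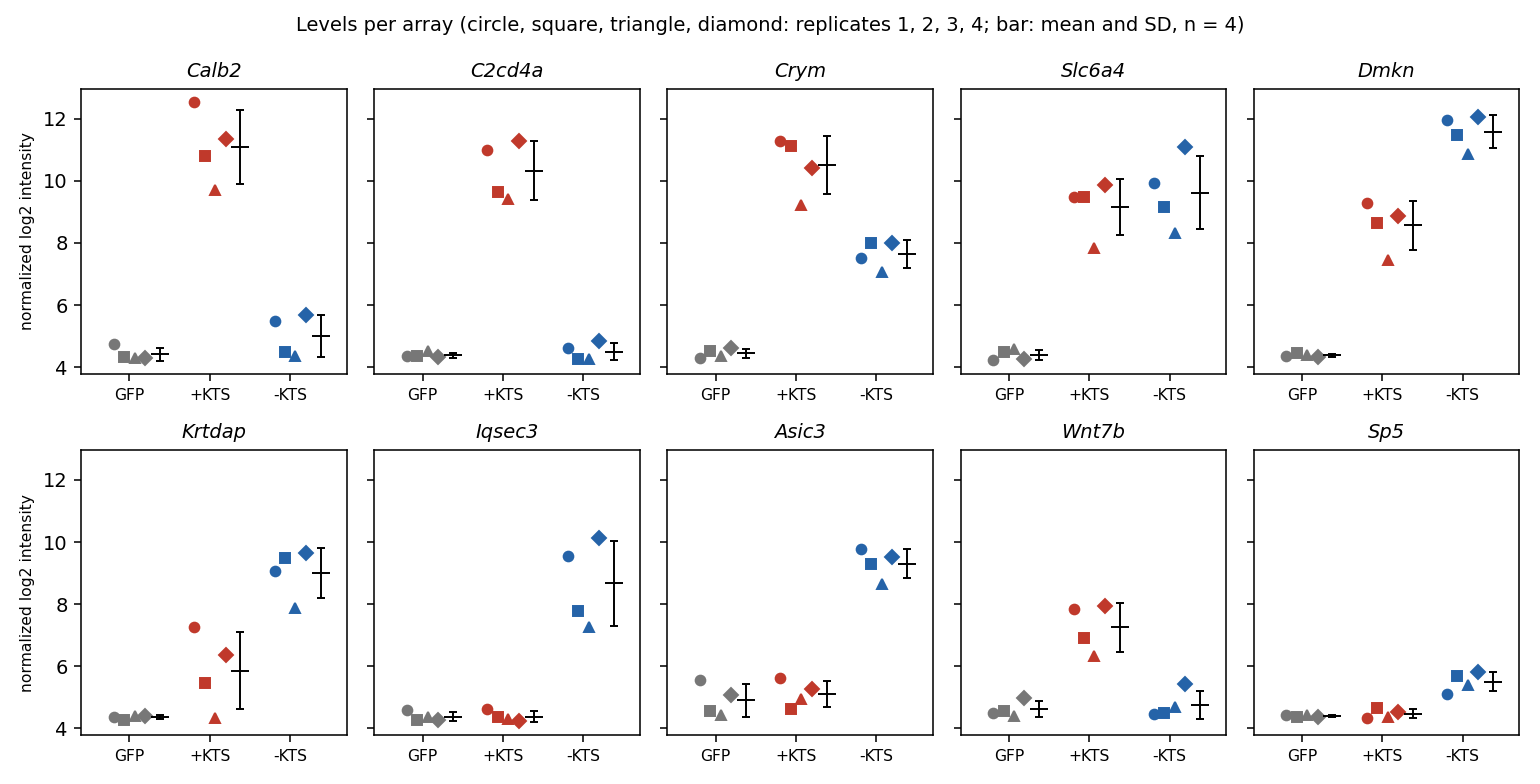
Normalised log2 intensity of 10 genes on each array, by group; symbols give the replicate number, and the bars give the mean and SD of 4 arrays. Calb2 and C2cd4a are high with EWS/WT1+KTS, Iqsec3 and Asic3 with EWS/WT1-KTS, and Crym, Slc6a4 and Dmkn with both.

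Of 20 Wnt/beta-catenin target genes 1 rose with EWS/WT1-KTS and 19 did not pass, and 2 passed adjusted over the list alone. Sp5, a transcription factor gene directly induced by beta-catenin, rose at least 1.50-fold, from a level not above background of 4.40 ± 0.04 (SD, n = 4) to 5.50 ± 0.31 (SD, n = 4), with an adjusted p of 0.0127. Its adjusted p lay between 0.0518 and 0.0654 without each of GFP replicate 2, GFP replicate 4, EWS/WT1-KTS replicate 2 and EWS/WT1-KTS replicate 4, and it did not pass without background correction (0.152), with a normexp offset of 50 (0.0851) or with median scaling (0.0954). With the replicate block the stem cell marker and Wnt receptor partner Lgr5 also rose (2.25 on the log2 scale, adjusted p = 0.00321; named after its value was seen). The target list was higher by camera (adjusted p = 0.00242), and the adjusted p was 0.252 with an estimated correlation. The ligand and receptor list did not pass (adjusted p = 0.414), with 0 of 20 genes called and 1, again Lgr5, adjusted over the list alone and in the blocked fit.

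Of 32 p53 target genes 0 passed over all genes or adjusted over the list alone, while 27 lay above 0 and camera called the list higher (adjusted p = 0.00105, and adjusted p = 0.252 with an estimated correlation). With the block 0 passed over all genes and 3 adjusted over the list alone. Cdkn1a, the p53 target that encodes p21, stood at 0.08 ± 0.25 (SE) by the probe used. By its 2 other kept probes it stood at 0.36 and 0.55. The 19 smooth muscle genes (adjusted p = 0.00105) and 7 Notch targets (0.00105) all lay above 0, and senescence-associated genes were also higher (0.0210), with adjusted p = 0.237, 0.237 and 0.271 with an estimated correlation. In these lists 0 genes passed over all genes, and 1, the Notch target Dtx4, passed adjusted over the list alone and also with the replicate block (adjusted p = 0.0366; named after its value was seen). Of 34 proliferation genes 0 passed over all genes or adjusted over the list alone, 7 lay above 0, and the list was lower (adjusted p = 0.0210, and adjusted p = 0.698 with an estimated correlation). With median scaling, which moved the median of all features to 0.10, the proliferation call ended and its median went from -0.11 to 0.02; the senescence call ended too. Of 10 reported EWS/WT1 targets 1 rose, Mlf1 (4.86-fold, adjusted p = 0.0311; named after its value was seen), and the list did not pass (adjusted p = 0.131). In the blocked fit Mlf1 also rose with EWS/WT1+KTS against GFP (log2 fold change 1.30, adjusted p = 0.00375). That fit also called Mlf1 higher with EWS/WT1-KTS than with EWS/WT1+KTS (0.99, adjusted p = 0.0238). With the block camera also called matrix genes higher and interferon response genes lower (adjusted p = 0.00597 each), with adjusted p = 0.598 and 0.609 with an estimated correlation. The interferon list's median log2 difference from GFP was -0.42, 0.01, 0.24 and -1.15 in replicates 1 to 4, so it was below 0 in replicates 1 and 4 only.

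The calls of EWS/WT1-KTS fell to 23 without GFP replicate 4 and also without EWS/WT1-KTS replicate 1. Without background correction the difference of Dmkn from its GFP signal at background shrank from 7.21 to 5.02 log2 units. The count was then 20, and it was 17 without the detection filter and 4 among features detected on all 12 arrays.

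The set fixed in advance also held Ccnd1, Myc, Ctnnb1, Cdkn2a, Pdgfa, Igf1r and Egr1. With Axin2 and Cdkn1a, 9 such genes were tested and 0 passed in any comparison by limma, also with the replicate block, where the lowest adjusted p was 0.294. Their log2 fold changes lay between -0.39 and 0.65 by the probes used. By other kept probes they ranged from -0.53, for Ccnd1 with EWS/WT1-KTS against GFP, to 0.80, for Cdkn2a with EWS/WT1+KTS against GFP. Lef1, a Wnt target and mediator, had 4 probes detected on at most 1 array and was not tested.

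The direct comparison of the isoforms tests whether their effects differ. Calb2, C2cd4a, Ccdc114, Gldn and Bpifb1 were lower with EWS/WT1-KTS than with EWS/WT1+KTS, with log2 fold changes of -6.10 ± 0.48 (SE) for Calb2, -5.83 ± 0.35 (SE) for C2cd4a and -5.25 ± 0.34 (SE) for Ccdc114, and at least 17.8-fold for Bpifb1. Iqsec3 was at least 13.9-fold and Cyp4f14 at least 14.1-fold higher with EWS/WT1-KTS, and Asic3 was 18.4-fold higher. Dmkn, which rose with both, was 8.14-fold higher with EWS/WT1-KTS (adjusted p = 0.000331), while Crym, which also rose with both, was lower by 2.87 log2 units (difference -2.87, adjusted p = 0.00102). Wnt7b was 5.58-fold lower with EWS/WT1-KTS (adjusted p = 0.00145), and Sp5, not above background with EWS/WT1+KTS, was at least 1.55-fold higher (adjusted p = 0.00926).

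Further genes higher with EWS/WT1-KTS were Krtdap (8.93-fold), Slc6a12 (8.37-fold), Cbln1 (8.17-fold), the matrix gene Matn4 (7.53-fold), Slpi (5.40-fold), the substance P precursor gene Tac1 (at least 4.11-fold), the semaphorin receptor gene Plxna2 (4.59-fold) and Dgkk (a log2 difference of 2.07 ± 0.40, SE). Further genes lower were Tmem51 (19.9-fold), Slc6a3 (at least 14.2-fold), Col23a1 (14.1-fold), Cpne6 (12.8-fold), the muscle Z-disc gene Pdlim3 (12.7-fold), the cornified envelope gene Lce3b (11.5-fold) and Tspan32 (at least 11.4-fold). Of the 4 EWS/WT1-KTS arrays 2 detected Calb2, Gldn, Col23a1 and Cpne6, 3 detected Ccdc114, and 1 detected C2cd4a, Lce3b and Wnt7b. Of the 4 EWS/WT1+KTS arrays 3 detected Asic3, Krtdap, Cbln1, Matn4 and Dgkk, and 2 detected Slc6a12. By another kept probe the log2 difference was -2.75 for C2cd4a, -1.89 for Ccdc114, -4.57 for Calb2, -2.76 for Col23a1 and 1.44 for Krtdap, and 0.19 for 1 further probe of Dmkn. The adjusted p of the 24 genes with the largest differences lay between 5.59e-07 and 0.0244. Dgkk did not pass without any 1 of EWS/WT1-KTS replicates 1, 3 and 4 and EWS/WT1+KTS replicates 1, 2 and 4, with adjusted p from 0.0712 to 0.110. Cbln1 did not pass without EWS/WT1-KTS replicate 1 (0.0520). Without background correction Cbln1, Tac1, Dgkk and Cpne6 did not pass, with a normexp offset of 50 Tac1 and Dgkk did not, and with median scaling Krtdap, Cbln1, Slpi, Cpne6 and Wnt7b did not.

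By limma 25 features were higher and 68 lower with EWS/WT1-KTS, and with the replicate block 106 were higher and 199 lower, including all 93 calls. With median scaling 15 were higher and 21 lower. The groups of all 93 did not overlap, and each call held its direction in all 4 pools, which the selection by that difference largely ensures. Of the 81 features that rose with EWS/WT1+KTS, 61 were also higher in it than in EWS/WT1-KTS, and of the 34 that rose with EWS/WT1-KTS, 20 were also higher in it than in EWS/WT1+KTS.

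Interferon response genes were lower with EWS/WT1-KTS as a list (adjusted p = 0.000519, and adjusted p = 0.644 with an estimated correlation), although 0 of 27 passed over all genes or adjusted over the list alone. All 27 lay below 0, with a median of -0.60. With the replicate block camera's adjusted p was 1.55e-10, the adjusted p was 0.411 with an estimated correlation, and 13 genes passed adjusted over the list alone. Macrophage markers did not pass (adjusted p = 0.0623) but did with the block (0.00421, and adjusted p = 0.411 with an estimated correlation), and 0 of 10 lay above 0. The block also gave calls for matrix genes (0.0116) and glycolysis and hypoxia genes (0.0297), both lower, with adjusted p = 0.515 and 0.411 with an estimated correlation. In the blocked fit 3 matrix genes (Eln, Mfap5 and Mgp), 1 macrophage marker (Laptm5) and 1 glycolysis gene (P4ha1) were lower, all named after their values were seen. Of 20 Wnt ligands and receptors 1, Wnt7b, was lower, and 2, with Wnt10b, passed adjusted over the list alone and in the blocked fit. That list was lower by camera (adjusted p = 0.00417, and adjusted p = 0.232 with an estimated correlation), its median of -0.19 turning to 0.03 with median scaling, which moved the median of all features to 0.27.

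**Figure D3:**
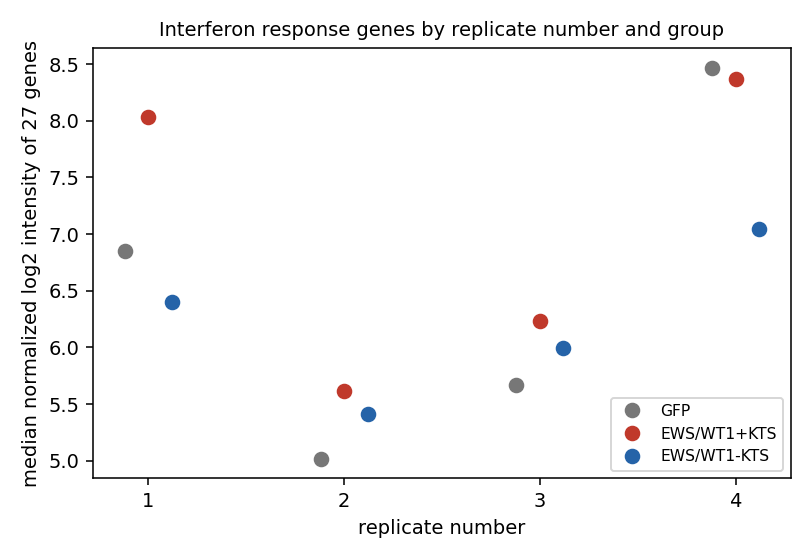
Median normalised log2 intensity of 27 interferon response genes on each array, by replicate number and coloured by group. Within every number EWS/WT1-KTS lies below EWS/WT1+KTS, while the arrays spread from 5.02 to 8.47 between numbers.

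The mesothelial list, in which 1 of 10 genes, Calb2, was lower, 1 passed adjusted over the list alone and 2, with Upk1b, in the blocked fit, was lower by camera (adjusted p = 0.0158, and adjusted p = 0.644 with an estimated correlation). Cholesterol synthesis genes, 0 of 21 called and 1 (Scd1) adjusted over the list alone and in the blocked fit, were lower (adjusted p = 0.0214, and adjusted p = 0.644 with an estimated correlation). Both medians turned above 0 with median scaling, to 0.03 and 0.13, and the cholesterol call ended. Smooth muscle genes, 0 of 19 called over all genes or adjusted over the list alone, were higher (adjusted p = 0.0214, and adjusted p = 0.578 with an estimated correlation), a call that ended with median scaling. Wnt10b, Upk1b and Scd1 were named after their values were seen.

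Both isoforms raised 5 genes: Dmkn, Slc6a4, Crym, Cpn1 and Pramel17. The unnamed probe was the only shared lower feature, and its call with EWS/WT1-KTS ended when any 1 array other than GFP replicate 3 was left out. Independent lists of the same sizes would share 0.22 on average. Simulated unchanged groups with shared simulated controls also shared 0. Because 0 features were called in those simulations, that count could not test whether shared controls create shared calls. With the GFP arrays split between the comparisons 3 or 4 genes were shared, and with the replicate block 29 were shared where independent lists would share 2.21. Slc6a4, Cpn1 and Pramel17 did not differ between the isoforms past the threshold, with log2 differences of 0.46, -0.18 and 0.52. Across genes, which are not independent replicates, fold changes of the isoforms correlated at r = 0.43, beside 0.50 for unchanged groups that share the controls. Their covariance was 0.0490 against 0.0158 simulated, an excess of 0.0332. With the GFP arrays split the covariance averaged 0.0272 for isoform arrays of the same numbers as their controls and -0.00732 for all isoform arrays. In the latter, differences between pools enter the fold changes of the isoforms with opposite signs and lower the covariance. That value therefore cannot tell whether the isoforms share effects.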

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

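The Dixon gap and the count of differing genes were computed by rules fixed in advance, and most tests weighed here were set down before their results were seen; the tests of brightness by pool and of the interferon list under median scaling were chosen only after. Among 120 groups of 4 arrays, 40 named genes in 3 groups, 6 had an array that stood apart, and chance flags about 6.

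Calb2 stood apart at 4.74 on GFP replicate 1 and Slc6a3 at 4.45 on GFP replicate 2, both undetected in every GFP sample. Ccnd1 stood apart at 12.49 on GFP replicate 2, where the nearest other array was at 11.94. Cdkn2a stood apart at 9.998 on EWS/WT1+KTS replicate 1, the nearest other at 9.14. Tac1 stood apart at 8.51 on EWS/WT1-KTS replicate 4, the nearest other at 6.52. Lce3b stood apart at 4.996 on EWS/WT1-KTS replicate 3, the 1 array of its group that detected it.

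The effects of the isoforms on the shared control differed for 93 features by limma, which the direct comparison tests. Of the 35 splits of those 8 arrays into 4 and 4, only the real split, 1 of 35, called as many, and the highest of the others called 4. For EWS/WT1+KTS against GFP 2 of 35 splits, the real one included, called at least its 82 features, and for EWS/WT1-KTS against GFP 2 of 35 called at least its 35, so over all splits chance was not excluded. The other split in each case set replicate numbers against each other and not groups. Replicates 1 and 2 against 3 and 4 called 1978, several times the real count, which points to a structure of the samples by replicate number. On those arrays the raw 75th percentile ran from 153.7 to 199.3 in replicates 1 and 2 and from 107.7 to 117.4 in 3 and 4. Pool and array processing therefore cannot be told apart there. In the other comparison replicates 1 and 4 against 2 and 3 called 39. Among the 8 splits that part all 4 pairs, as the real one does, the others called 0 in each comparison, also with the replicate block, where the real splits called 280 and 130.

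The genes that rose from background with an isoform were set against an array with a wrong label and against brighter isoform arrays. With genes called from the other 3 pools, 12 of 12 arrays lay nearest to their own group, which argues against a swapped label within these arrays. In 6 of 8 pairs of arrays with the same number the isoform array had a lower 75th percentile of raw intensity than its GFP array, and in each of these pairs the genes called higher from the other 3 pools rose. Their median rise was 2.75 log2 units, with 227 of 237 above 0 and 93 of 103 in the weakest pair (EWS/WT1+KTS replicate 3, median 0.98), which argues against brighter isoform arrays as their cause. An effect of the fusion proteins themselves is the open biological explanation, and this series holds no second vector or clone to test it.

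The lower interferon response list with EWS/WT1-KTS than with EWS/WT1+KTS was tested against a single pool and a shift of all genes. The median difference was -0.96, -0.11, -0.10 and -0.90 in replicates 1 to 4, and the weakest value with 1 pool left out was -0.387. With median scaling the list stood at -1.20, -0.0097, -0.0015 and -0.16, and at -0.08 without replicate 1, but that scaling raised all features by 0.27, and less all features the weakest value with 1 pool left out was -0.44, which argues against 1 pool as the whole cause, though replicates 1 and 4 carry most of the size. Quantile normalisation holds the median over all features near 0, so a general shift was tested with median scaling too: the list at -0.40 lay -0.675 from all features, and below them in every pool, which argues against a general shift. Against GFP the list's median was 0.69, 0.03, 0.34 and 0.05 with EWS/WT1+KTS in replicates 1 to 4. With EWS/WT1-KTS it was -0.42, 0.01, 0.24 and -1.15. A difference in vector dose or in the state of the cultures was not tested and stays open beside an effect of the isoform.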

How the results depend on the processing

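Alternatives chosen after seeing the data were the replicate number as a random effect, the replicate block within some of the numbers, and fry and the estimated correlation with the block; all others were planned, and chip as a block was not run because no chip is named. Counts are given for EWS/WT1+KTS against GFP (82), EWS/WT1-KTS against GFP (35) and EWS/WT1-KTS against EWS/WT1+KTS (93), in that order where 3 stand together. Values from the authors' log2 table gave the same counts.

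Without background correction the GFP comparisons gave 51 and 20, and with a normexp offset of 50 the second gave 23. Median scaling gave 30, 21 and 36, and it moved the median of all features to -0.17, 0.10 and 0.27, so medians of lists that turned sign with it moved with all features. No detection filter gave 49 and 17 in the GFP comparisons, and detection on all 12 arrays, which leaves out the genes silent in the control, gave 14, 4 and 16. The 8 compared arrays alone, with fewer arrays behind the spread, gave 52 in the first. The replicate block raised the counts to 280, 130 and 305, and the random effect to 235, 114 and 282, since the spread between pools leaves the error. With the block, replicates 1 and 2 gave 315, 104 and 309, replicates 3 and 4 gave 28, 7 and 21, and all but number 2 gave 153, 68 and 160. Among the counts of single arrays left out the ranges were 51 to 116, 23 to 51 and 74 to 130; all calls at each lowest count were among those of the full data. Apart from explanations named, the cause was not tested.

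Camera called 11, 6 and 5 lists. With an estimated correlation and with fry 0 were called in each comparison, and the replicate block raised the last to 8; with the block fry called 5, 5 and 0 and the estimated correlation 0 in each. With single arrays left out the ranges were 5 to 11, 4 to 11 and 4 to 6; the count for EWS/WT1+KTS was 6 without GFP replicate 3, 7 without EWS/WT1+KTS replicate 1 and 5 without its replicate 4, and that for EWS/WT1-KTS was 11 without GFP replicate 3. The isoforms shared 6 calls, the unnamed probe included, 2 without background correction and 34 with the replicate block, with a range of 5 to 7 over arrays left out.

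No named gene reversed in a comparison where it passed in the main or the alternative fit. Changes of sign in pairs that passed in neither were not counted. Of 51 called gene and comparison pairs, 38 passed under every alternative run for single genes, and the replicate block changed no call among the 78 pairs. Signal over background limits the genes undetected in a group, whose folds by the probe used are given as bounds. Log2 differences of other probes are given as measured, without a bound.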

Other observations

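The tests of neighbouring genes by random placement were set down before their result was seen, although Iqsec3 and Slc6a12 had by then been listed among the calls; the matched draws and the comparisons of pools were chosen after the data were seen.

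The replicate numbers differed more than the groups. They accounted for 57.8% of the variance over all features and groups for 21.9%, and 5519 features differed between replicate numbers by limma with groups in the model. Brightness differed too: the raw 75th percentile ran from 153.7 to 199.3 in replicates 1 and 2 and from 107.7 to 151.3 in 3 and 4. In these values pool and array processing cannot be told apart. Xist, transcribed from the inactive X chromosome, was at 8.77, 7.68 and 7.53 with GFP in replicates 1, 3 and 4 and at 4.27 in replicate 2. By 1 probe the Y-linked Eif2s3y was at 7.24 with GFP in replicate 2 and undetected in the other numbers, while another of its probes was detected on no array. A probe of the Y-linked Uty did not differ in that way, at 5.05, 5.30, 5.13 and 5.38 with GFP in replicates 1 to 4. Macrophage markers were highest in replicate 3, with an average of the 3 arrays' list medians of 6.93 against 5.10, 5.13 and 5.22 in replicates 1, 2 and 4. The same average for interferon response genes ranged from 5.35 in replicate 2 to 7.96 in replicate 4.

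Replicate 3 had the smallest rise in 70 of the 81 features that rose with EWS/WT1+KTS and in 29 of the 34 that rose with EWS/WT1-KTS. Taken against the GFP signal as measured, background included, the median rise with EWS/WT1+KTS was 1.43 log2 units in replicate 3 and 2.91, 2.55 and 2.36 in replicates 1, 2 and 4. With EWS/WT1-KTS it was 1.70 in replicate 3 and 2.83, 2.17 and 3.37 in the others. No explanation for this was tested.

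Some genes that rose were next to each other in order among the tested genes. Distances were not measured, and genes not tested can lie between. Dmkn and Krtdap share a locus, and Sbsn beside them, which did not pass, stood at 2.72 ± 0.68 (SE) with EWS/WT1-KTS and was named after its value was seen. With that locus left out, 7 pairs of the 90 remaining named genes that rose with either isoform were direct neighbours among 10110 tested genes: Popdc3 and Bves, Pcdh8 and Pcdh17, Synj2 and Serac1, Sp5 and Gad1, Slpi and Matn4, Cda and Camk2n1, and Slc6a12 and Iqsec3. Random draws of as many genes gave 0.79 pairs on average and at most 6 in 10000 draws, which argues against chance placement of the called genes. Without Iqsec3 and Slc6a12, listed before the test, 6 pairs were left, and a share of 1e-04 of the draws gave as many. Draws were also matched on the GFP level in 10 bins, and they gave 0.85 on average and again at most 6. The bins are broad and mix silent with weakly expressed genes, and genes undetected on all arrays were not tested. These draws therefore cannot tell whether genes silent in these fibroblasts lie together. A hypothesis is that the fusion may act on stretches of a chromosome that hold more than 1 gene. Binding of the fusion was not measured, and co-regulated neighbours that respond to many stimuli stay open.

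Neighbours mostly moved with the same isoform. Popdc3 and its paralogue Bves, which encode membrane proteins of muscle, rose with EWS/WT1+KTS at least 6.20-fold and 7.06-fold, and Bves stood at a log2 fold change of -0.02 with EWS/WT1-KTS. Slpi and Matn4 rose with EWS/WT1-KTS by 2.90 and 2.87 log2 units and stood at 0.47 and -0.04 with EWS/WT1+KTS. Sp5 and Gad1, the gene of a GABA-synthesising enzyme, rose with EWS/WT1-KTS at least 1.50-fold and at least 2.31-fold. Pcdh8 and Pcdh17 were the exception, the former at least 2.51-fold higher with EWS/WT1+KTS and the latter 3.41-fold higher with EWS/WT1-KTS. These genes were chosen after their values were seen.

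Lists for epithelial genes, neural genes, endothelial markers, reported WT1 targets and housekeeping genes passed in 0 of the 3 comparisons by camera without the block, and 0 of their members were called in that fit. With the replicate block the WT1 targets Tgfb1 and Vdr were higher with EWS/WT1+KTS than with GFP, Tgfb1 was lower with EWS/WT1-KTS than with EWS/WT1+KTS, and the neural gene Stmn2 was lower with EWS/WT1-KTS than with GFP; these were named after their values were seen.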
